A study of Rattus norvegicus with 12 samples.

How the data were processed

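Total RNA of the myofascial layer of the rat anterior abdominal wall was measured on 12 Affymetrix Rat Gene 2.1 ST arrays. The arrays fall into 4 groups of 3 by mesh (conventional or silver-containing polypropylene) and by inoculation with Staphylococcus aureus. Per the labels' protocols, each array held equal amounts of RNA of 3 animals of its group, and each group had 4 animals. If the 3 different pools of a group were drawn from those 4 animals, any 2 of its pools share 2 animals, 1 animal is in all 3 pools, and no animal is in only 1. The pools are then not independent, and p-values over pools are too small. Which animals entered which pool is not given in the sources used here.

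The authors deposited log2 values made with RMA (background correction, quantile normalization and summarisation of probes per transcript cluster), as named in the submitters' processing notes without a version. The software, the filters and the scan batches are not given in the sources used here. The table holds 35933 values per array, and array medians lay within 0.07 log2 units of each other. Signal relative to background was not used here, so a low value cannot be told from no signal, and the number of arrays limits the precision. The probe annotation gives 1 gene symbol for 14802 of these transcript clusters, several for 817 and none for 20314. Clusters with several symbols or none were left out of the main tests. Entrez identifiers of 14648 of the 14802 were found in the RefSeq gene table of assembly GRCr8, and 0 of their symbols differed. For 219 genes with several clusters, the cluster with the highest mean over the 12 arrays was taken, which left 14557 genes.

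Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit with 4 group means, contrasts and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 14557 genes and a threshold of 0.05 on the adjusted p. The fit had 8 residual degrees of freedom and 4.13 prior ones. The comparisons were infection within each mesh, silver against conventional mesh within each infection state, and the interaction, which is the silver difference in infected tissue minus that in non-infected tissue. For 31 gene lists fixed before the data were examined, naming 594 members of which 438 list places were measured, camera was run with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. Changes are log2 differences with the standard error (SE) of the limma fit, and group levels are means with the SD of 3 pools.

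The genes named follow a rule set before the data were examined. It takes the 10 largest rises and 10 largest falls past the threshold with groups that do not overlap (5 and 5 for the interaction), up to 4 members past the threshold of each list called or with at least 3 such members (or, if no member passes, the 2 with the largest change), and the reference genes S100a8, S100a9, Il1b, Tlr2, Col1a1, Acta1, Adipoq, Krt14 and Mt2A. Mt1a, also in the rule, is not named in the annotation used. Symbols of predicted models, microRNA and small nucleolar RNA were skipped. Any gene named outside the rule is said to be so.

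Alternatives were quantile normalization again, centring of each array on its median, leaving out the dimmest 30% of genes, all transcript clusters, the mean over the clusters of a gene, a trended and robust variance prior, only the groups compared in the fit, a minimum fold of 1.5, the replicate number as a block, array weights, each array left out in turn, and pools of a group correlated by 0.667, the value that follows if all spread lies between the 4 animals. The last raises each SE by 2.65 times. Added after seeing the data were a fit with a correlation of 0.0825, which duplicateCorrelation (statmod 1.5.0) gave as the consensus over genes with no group term and which raises each SE by 1.13 times, and a fit without intestinal genes. Treatment effects count towards that consensus too, and it was not shown to be an upper bound on the correlation due to animals.

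The limma step was tested on simulated data with the means and spreads of the 14557 genes, 200 of them changed. For the silver minus conventional comparison in infected tissue it recovered 90.4% of genes changed by 1 log2 unit and 99.5% of those changed by 2, and 5.95% of its calls were false. For the interaction it recovered 59.0% and 98.7%, with 4.37% of calls false. These rates are for pools and genes drawn independently and need not hold for pools that share animals. In the same infected comparison with no effect and all spread between 4 animals pooled as above, limma with independent pools called a mean of 4586.8 genes, and with the correlation of 0.667 it called 0. Those simulations gave 43.0% of genes an unadjusted p under 0.05, against 7.01% in the data, so 0.667 is an extreme rather than the correlation of most genes.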

Results

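The data describe tissue around surgical mesh in 7-week-old male Sprague-Dawley Hairless rats, explanted 10 days after implantation of a conventional polypropylene mesh or a polypropylene mesh containing 250 ppm silver. In each mesh arm 4 animals received 10000000 colony-forming units of Staphylococcus aureus Xen 29 on the mesh and 4 did not. Each of the 4 groups was measured on 3 arrays, each a pool of 3 animals. The labels imply that pools of a group share animals, so p-values over pools are too small. Expression profiles were close to each other, with a mean correlation across genes of 0.990 between arrays of a group and 0.988 between groups. Values are authors' RMA log2 values, and ± after a change is its SE with 3 pools per group.

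The first comparison asks how infection changed tissue around the conventional mesh. Infected tissue had higher expression of Scd, a desaturase of fatty acid synthesis (1.90 ± 0.27 log2), and of Aspn, a small leucine-rich proteoglycan of the matrix (1.37 ± 0.19). Tceal7 (1.14 ± 0.12), Fndc1, a protein with fibronectin type III domains (1.05 ± 0.14), the tetraspanin Tspan18 (0.88 ± 0.12) and Galnt16, a transferase that starts O-glycosylation (0.87 ± 0.10), also rose. Chac1, a glutathione-degrading enzyme induced by the unfolded protein response, fell by 1.55 ± 0.20, and Pfkfb3, an activator of glycolysis, fell by 1.30 ± 0.12. These 8 genes, 6 higher and 2 lower, were all that passed the threshold (limma, Benjamini-Hochberg adjusted p from 0.00295 for Pfkfb3 to 0.0254 for Scd). For each the 3 infected pools lay beyond the 3 non-infected ones, a separation chance gives 10% of genes if pools are independent. Every gene called in any comparison of 2 groups was separated in this way, so the separation adds no support to the calls.

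Interferon-stimulated genes, which are induced by antiviral and inflammatory cytokines, rose as a list with the infected conventional mesh. All 21 measured members had values above 0, with a median of 0.59 log2. Mx1 (2.01 ± 0.36, adjusted p = 0.0848 with limma) and Isg15 (1.31 ± 0.30, adjusted p = 0.146) had the largest changes, and 0 members passed over all genes against 10 adjusted over the list alone. The list's call (camera, Benjamini-Hochberg adjusted p = 3.73e-12) was lost with adjusted p = 0.376 with an estimated correlation. The list of MHC class II antigen presentation rose with a median of 0.27 (camera adjusted p = 0.000777, and adjusted p = 0.376 with an estimated correlation), led by RT1-Ba (0.62 ± 0.11) and RT1-Bb (0.45 ± 0.13), neither past the threshold. Fibrillar collagen and matrix had a median of 0.13 (camera adjusted p = 0.00223, and adjusted p = 0.895 with an estimated correlation), with Eln, the gene of elastin, at 0.52 ± 0.15 and the proteoglycan Fmod at -0.57 ± 0.20. The foreign-body giant cell list had a median of 0.33, with Atp6v0d2 at 0.88 ± 0.20 and Gpnmb at 0.56 ± 0.25. The muscle regeneration list had a median of 0.36, with Ankrd1 at 1.96 ± 0.56 and Myh3, the embryonic myosin, at 1.57 ± 0.61. Both were called by camera (adjusted p = 0.0129 each) and lost, each with adjusted p = 0.376 with an estimated correlation. With 1 array left out, camera called each in 9 of 12 fits, with a largest adjusted p of 0.0929 and 0.121. Without conventional non-infected replicate 1 the median was 0.15 for MHC class II and 0.55 for muscle regeneration. None of these 6 members passed the limma threshold.

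With pools correlated by 0.667, limma called 0 genes for infection with the conventional mesh (15 at an unadjusted p under 0.05, against 1320 with independent pools and 728 by chance), and with the consensus correlation of 0.0825 it called 3. A trended robust prior called the most, 57. With 1 array left out the count lay between 1, without infected conventional replicate 1, and 20, without non-infected silver replicate 2.

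Many of the genes that rose with infection around the silver mesh are given here in groups made after their values were seen. Genes best known from intestinal epithelium included the C-type lectins Reg3g (3.01 ± 0.20 log2), Reg4 (2.35 ± 0.25) and Reg3b (2.20 ± 0.17), the Paneth cell defensins Defa8 (2.52 ± 0.14) and Defa9 (1.97 ± 0.17), and Fabp6, the ileal bile acid binding protein (2.43 ± 0.23). Interferon-induced genes included Mx1 (2.44 ± 0.36), the chemokines Cxcl10 (1.95 ± 0.26) and Cxcl11 (1.69 ± 0.21), Slfn4 (1.84 ± 0.31) and Isg15 (1.77 ± 0.30). Genes known from lymphocytes and macrophages included Klrk1, an activating receptor of natural killer cells (1.56 ± 0.22), Jchain, the joining chain of polymeric antibodies (1.13 ± 0.17), Ccl5, a chemokine of T cells (0.98 ± 0.13), Siglec1, a macrophage adhesion receptor (0.91 ± 0.15), and the MHC class II gene RT1-Ba (0.62 ± 0.11). Other genes that rose, such as Tceal7 (0.82 ± 0.12), belong to none of these groups. The intestinal genes named had means between 1.58 and 3.26 in the other groups, where a low value cannot be told from no signal, so the order of their changes is not a ranking. The changes of all these groups come from the same 3 infected silver arrays, and intestinal RNA in those pools was not excluded. Only 3 genes fell: the receptor subunit Gabrr2 by 0.83 ± 0.14, Pfkfb3 by 0.73 ± 0.12 and the potassium channel gene Kcnb2 by 0.67 ± 0.11. In all, 47 genes passed, 44 higher and 3 lower (limma, Benjamini-Hochberg adjusted p from 6.44e-06 for Defa8 to 0.0430 for RT1-Ba among the genes named).

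Of the gene lists, 12 rose and 2 fell with infection around the silver mesh. The natural killer and cytotoxic cell list had all 13 measured members above 0, with a median of 0.96 log2 (0.54 without silver infected replicate 1), and the T cell list 17 of 18, with a median of 0.30. These 2 lists also passed in camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.0403 each). Fry called them and the interferon-stimulated and MHC class II lists (adjusted p = 0.00756 each), as well as the B cell and plasma cell list (0.0441). With pools correlated by 0.667, fry called 0 lists in every comparison (0 at an unadjusted p under 0.05), and the adjusted p of the T cell and natural killer lists was 0.738. Within the T cell list Cd8a, the co-receptor of cytotoxic T cells, changed by 1.11 ± 0.29 and Cd2 by 0.67 ± 0.39, neither past the threshold. The interferon-stimulated list had a median of 1.03, with all 21 members above 0, 6 past the threshold over all genes and 19 adjusted over the list alone (camera adjusted p = 1.04e-29, and adjusted p = 0.0604 with an estimated correlation). MHC class II antigen presentation had a median of 0.33 (camera adjusted p = 6.22e-08, and adjusted p = 0.0604 with an estimated correlation), and the B cell and plasma cell list 0.20 (camera adjusted p = 0.00271, and adjusted p = 0.132 with an estimated correlation).

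Myeloid lists rose too, though few of their members passed. The macrophage list had a median of 0.33 with 17 of 17 members above 0, the classically activated macrophage list 0.42 with 13 of 13, the bacterial sensing list 0.30, and the inflammatory cytokines and chemokines 0.55. Their camera adjusted p lay between 2.05e-07 and 2.67e-06, and all 4 calls were lost, with adjusted p = 0.250, 0.178, 0.260 and 0.338 with an estimated correlation. The cytokine median was 0.23 without silver non-infected replicate 2, and 0.30 and 0.36 without silver infected replicates 1 and 2. That of classically activated macrophages was 0.65 without silver non-infected replicate 1 and 0.69 without silver infected replicate 3. In the bacterial sensing list the endosomal RNA sensor Tlr7 changed by 0.85 ± 0.19 and Tlr6 by 0.66 ± 0.22, short of the threshold. The neutrophil list had a median of 0.35 (camera adjusted p = 0.0199, and adjusted p = 0.528 with an estimated correlation), with the antibacterial Lcn2 at 1.60 ± 0.78 and the calprotectin subunit S100a9 at 0.89 ± 0.94. Its call was lost without silver non-infected replicate 2 (median 0.14, camera adjusted p = 0.682) and without silver infected replicate 1 (0.37, 0.122) or 2 (0.31, 0.251), and its median was 0.57 without silver non-infected replicate 1 and 0.64 without silver infected replicate 3. Complement had a median of 0.27 (camera adjusted p = 0.00197, and adjusted p = 0.260 with an estimated correlation), with C3 at 1.00 ± 0.20 and C3ar1 at 0.53 ± 0.18. The cell cycle list also had a median of 0.27 (camera adjusted p = 0.000147, and adjusted p = 0.260 with an estimated correlation), with Cdk1 at 0.61 ± 0.20 and Plk1 at 0.50 ± 0.20. The adipocyte list fell with a median of -0.28 (camera adjusted p = 0.000739, and adjusted p = 0.335 with an estimated correlation), with Cidec at -0.93 ± 0.35 and Retn at -0.89 ± 0.30. Its call was lost without silver non-infected replicate 2 (median -0.14, camera adjusted p = 0.106). Oxidative phosphorylation and citrate cycle fell with a median of -0.11 (camera adjusted p = 0.00898, and adjusted p = 0.528 with an estimated correlation), with Cox8b at -0.34 ± 0.14 and Ndufv1 at -0.25 ± 0.15. That call was lost without the same 3 arrays as the neutrophil call (medians -0.013, -0.060 and -0.067, camera adjusted p = 0.645, 0.212 and 0.0854). Its median was -0.20 without silver non-infected replicate 1 or silver infected replicate 3. None of the members named in this paragraph passed the threshold.

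For the infected silver mesh, limma with pools correlated by 0.667 called 0 genes (33 at an unadjusted p under 0.05, against 1350 with independent pools and 728 by chance, smallest adjusted p 0.281). With the consensus correlation it called 15, all higher, against 47 with independent pools, and array weights called the most, 267. Leaving out the intestinal genes, an alternative added after seeing the data, left 22 of the 36 other genes called. The log2 changes of all 36 stayed as they were, and the adjusted p of those lost rose to between 0.0514 and 0.0634. With 1 array left out the count lay between 12, without infected silver replicate 1 or 3, and 62, without its replicate 2.

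**Figure D1:**
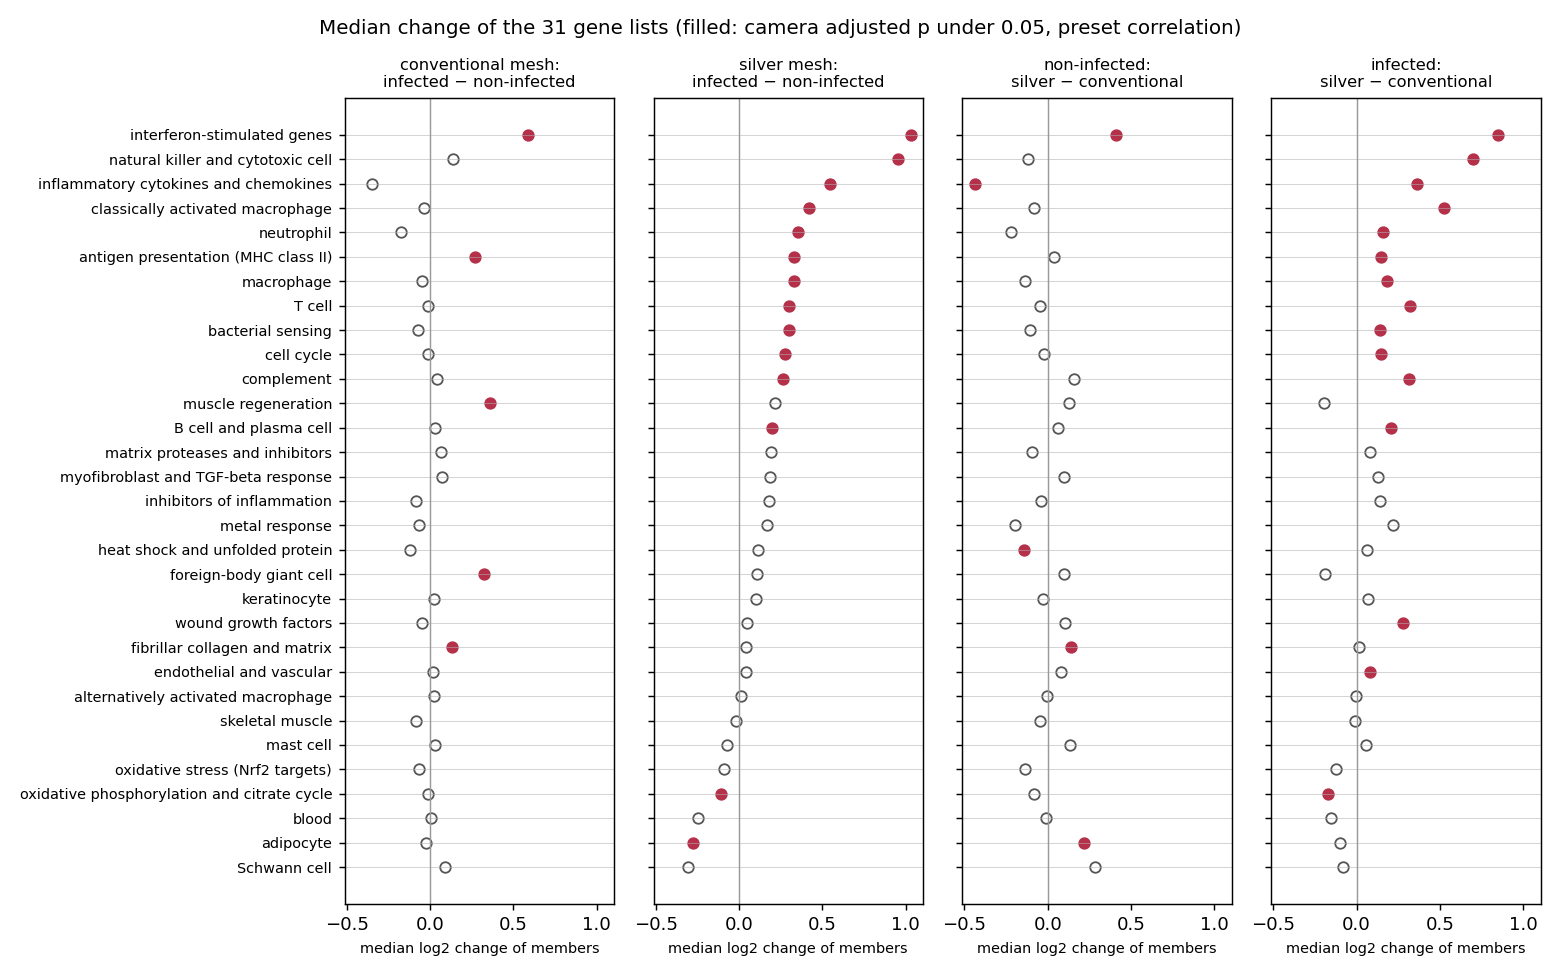
Each point is the median log2 change of the measured members of 1 of the 31 gene lists, with the change on the horizontal axis and 1 panel per comparison. Filled points had a camera adjusted p under 0.05 with the preset correlation, and all but the T cell and natural killer lists in the silver mesh panel lost that call with an estimated correlation. The interferon-stimulated list lies at 0.59, 1.03, 0.41 and 0.85 in the 4 panels.

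The next comparison asks how the silver mesh differed from the conventional mesh without infection. Scd was higher by 2.07 ± 0.27 log2, while Igfn1, a protein of skeletal muscle sarcomeres, fell by 1.57 ± 0.14 and Chac1 fell by 1.51 ± 0.20. These 3 genes were all that passed (limma, Benjamini-Hochberg adjusted p = 0.0307, 0.00163 and 0.0307). With 1 array of these groups left out, Igfn1 was called in 6 of 6 fits, Scd in 2 and Chac1 in 0. With any 1 array left out the count lay between 1 and 6. An unadjusted p under 0.05 was found for 1466 genes against 728 by chance, more than in any of the other 4 comparisons. Without the dimmest 30% of genes 13 passed, with a trended robust prior 14 and with array weights 17. Mt2A, a metallothionein that binds metal ions, was at -0.94 ± 0.47 (adjusted p = 0.527 with limma), and the metal response list had a median of -0.20 (camera adjusted p = 0.361). The list of oxidative stress genes had a median of -0.14 (camera adjusted p = 0.0596).

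Among lists, the interferon-stimulated genes rose with the silver mesh in non-infected tissue, with 20 of 21 members above 0 and a median of 0.41 log2 (camera adjusted p = 3.69e-09, and adjusted p = 0.749 with an estimated correlation). Mx1 (1.32 ± 0.36) and Irf7, a transcription factor of the interferon response (1.32 ± 0.39), had the largest values and did not pass. Fibrillar collagen and matrix rose with a median of 0.14 (camera adjusted p = 0.00109, and adjusted p = 0.749 with an estimated correlation), with Thbs2 at 0.58 ± 0.24 and Eln at 0.47 ± 0.15, neither past the threshold. The call was lost without silver non-infected replicate 1 (median 0.055, camera adjusted p = 0.0642), and without its replicate 2 the median was 0.23. The adipocyte list rose with a median of 0.22 (camera adjusted p = 0.0140, and adjusted p = 0.749 with an estimated correlation), Scd being its only member past the threshold over all genes, against 2 adjusted over the list alone. Without silver non-infected replicate 2 it was not called (camera adjusted p = 0.355). Inflammatory cytokines and chemokines fell with a median of -0.44 (camera adjusted p = 0.00656, and adjusted p = 0.768 with an estimated correlation), with Il6 at -1.50 ± 0.73 and the neutrophil attractant Cxcl2 at -1.19 ± 1.09, neither past the threshold. This call was lost without conventional non-infected replicate 2 (median -0.24, camera adjusted p = 0.502) and without silver non-infected replicate 2 (-0.21, 0.358). Without conventional non-infected replicate 1 the median was -0.93. Heat shock and unfolded protein genes fell with a median of -0.14 (camera adjusted p = 0.00656, and adjusted p = 0.749 with an estimated correlation), with only Chac1 past the threshold. With pools correlated by 0.667, limma called 0 genes in this comparison (13 at an unadjusted p under 0.05), and with the consensus correlation only Igfn1 passed (adjusted p = 0.00606).

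In infected tissue, the silver mesh had higher expression of genes of the same groups. Here too, intestinal RNA in the infected silver pools was not excluded as a source of the intestinal ones. The intestinal genes included Reg3g (2.99 ± 0.20 log2), Fabp6 (2.37 ± 0.23), Defa8 (2.36 ± 0.14), Reg4 (2.30 ± 0.25), Reg3b (2.18 ± 0.17), Defa9 (2.14 ± 0.17) and Agr2, a disulfide isomerase of mucus-secreting cells (1.80 ± 0.20). Interferon-induced genes included the GTPase Gbp1 (1.78 ± 0.29), Ifit3 (1.64 ± 0.27) and Cxcl11 (1.29 ± 0.21). Genes known from immune cells included Ly6c, a surface antigen of monocytes and other leukocytes (1.73 ± 0.25), Klrk1 (1.34 ± 0.22), Jchain (1.11 ± 0.17), Ccl5 (1.06 ± 0.13) and Siglec1 (1.03 ± 0.15). Gabrr2 fell by 0.84 ± 0.14 and the cytochrome P450 gene Cyp4f5 fell by 0.74 ± 0.13. In all, 24 genes passed, 22 higher and 2 lower (limma, Benjamini-Hochberg adjusted p from 1.37e-05 for Defa8 to 0.0475 for Cyp4f5). Of the 22, 18 were also among the genes that rose with infection around the silver mesh, a comparison that shares the infected silver arrays. Independent calls would share 0.0665, and the covariance of the changes across genes was 0.0322 against 0.0158 in simulations with no effect, an excess that may in part come from the shared arrays.

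Of the lists, 14 were higher and 1 lower around the infected silver mesh than around the infected conventional mesh. Interferon-stimulated genes had a median of 0.85 with 21 of 21 members above 0, 2 past the threshold over all genes and 19 adjusted over the list alone (camera adjusted p = 2.02e-32, and adjusted p = 0.0531 with an estimated correlation). The natural killer and cytotoxic cell list had a median of 0.70 and the T cell list 0.32 (camera adjusted p = 6.86e-11 and 4.08e-06, and adjusted p = 0.0514 for both with an estimated correlation), with Cd8a at 0.89 ± 0.29 and Cd2 at 0.86 ± 0.39, neither past the threshold. Complement had 10 of 10 members above 0 and a median of 0.31 (camera adjusted p = 2.36e-06, and adjusted p = 0.0843 with an estimated correlation), with C1qc at 0.43 ± 0.13 and Serping1 at 0.43 ± 0.13. B cell and plasma cell genes had a median of 0.21, or 0.13 without conventional infected replicate 3 (camera adjusted p = 0.000267, and adjusted p = 0.0680 with an estimated correlation). Wound growth factors had a median of 0.28 (camera adjusted p = 0.0141, and adjusted p = 0.107 with an estimated correlation), with Ereg at 0.42 ± 0.21 and Wnt5a at 0.36 ± 0.18. The call was lost without conventional infected replicate 1 or silver infected replicate 2 (medians 0.15 and 0.20, camera adjusted p = 0.0980 and 0.0653). In fry these 6 lists passed, with adjusted p from 0.0147 to 0.0236. Oxidative phosphorylation and citrate cycle was lower with a median of -0.17 (camera adjusted p = 0.000153, and adjusted p = 0.425 with an estimated correlation), with Ppargc1a, a regulator of mitochondrial genes, at -0.41 ± 0.18 and Cox8b at -0.35 ± 0.14. The C1qc, Serping1, Ereg, Wnt5a, Ppargc1a and Cox8b differences did not pass the limma threshold.

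The remaining lists called in infected tissue were myeloid, vascular and proliferative. Macrophage genes had a median of 0.18, classically activated macrophage 0.53, inflammatory cytokines and chemokines 0.36, neutrophil 0.16, bacterial sensing 0.14, MHC class II antigen presentation 0.14, endothelial and vascular 0.08 and cell cycle 0.14. Their camera adjusted p lay between 4.6e-05 and 0.0141, and each call was lost, with adjusted p = 0.334, 0.239, 0.425, 0.511, 0.461, 0.239, 0.425 and 0.425 with an estimated correlation. With 1 array left out camera called neutrophil and vascular genes in 9 of 12 fits, cell cycle genes in 10 and MHC class II genes in 11. Without conventional infected replicate 3, silver infected replicate 1 and silver infected replicate 2, the median of classically activated macrophage genes was 0.29, 0.30 and 0.32 and that of cytokines 0.17, 0.20 and 0.23. The neutrophil median was 0.38 and 0.082 without conventional infected replicates 1 and 3, and 0.10 and 0.41 without silver infected replicates 1 and 3. Without silver infected replicate 3 that of bacterial sensing was 0.22 and that of vascular genes 0.14, and without its replicate 2 that of the cell cycle was 0.056. Members named that did not pass were Il6 (1.41 ± 0.73) and Cxcl10 (1.21 ± 0.26) among macrophage activation genes, Lcn2 (1.81 ± 0.78) and S100a9 (1.06 ± 0.94) among neutrophil genes, and Lbp (0.56 ± 0.39) and Tlr7 (0.49 ± 0.19) in bacterial sensing. Others were Flt3 (0.70 ± 0.27) and RT1-DOa (0.38 ± 0.16) in antigen presentation, Selp (1.03 ± 0.37) and Plvap (0.32 ± 0.15) in vessels, and Rrm2 (0.45 ± 0.23) and Cdk1 (0.36 ± 0.20) in the cell cycle. The macrophage gene Siglec1 and the chemokine gene Ccl5 were the only members of these lists past the limma threshold over all genes. The metal response list had a median of 0.22 (camera adjusted p = 0.142) and the oxidative stress list -0.12 (adjusted p = 0.151). With pools correlated by 0.667, limma called 0 genes between the infected meshes (24 at an unadjusted p under 0.05, against 1021 with independent pools, smallest adjusted p 0.524), and with the consensus correlation 9, all higher. Without the intestinal genes only Ccl5 passed (1.06, limma adjusted p = 0.0421). The other 12 genes kept their log2 changes, and their adjusted p rose to between 0.0831 and 0.0875. With 1 array left out the count lay between 8, without infected conventional replicate 3, and 39, without infected silver replicate 2.

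**Figure D2:**
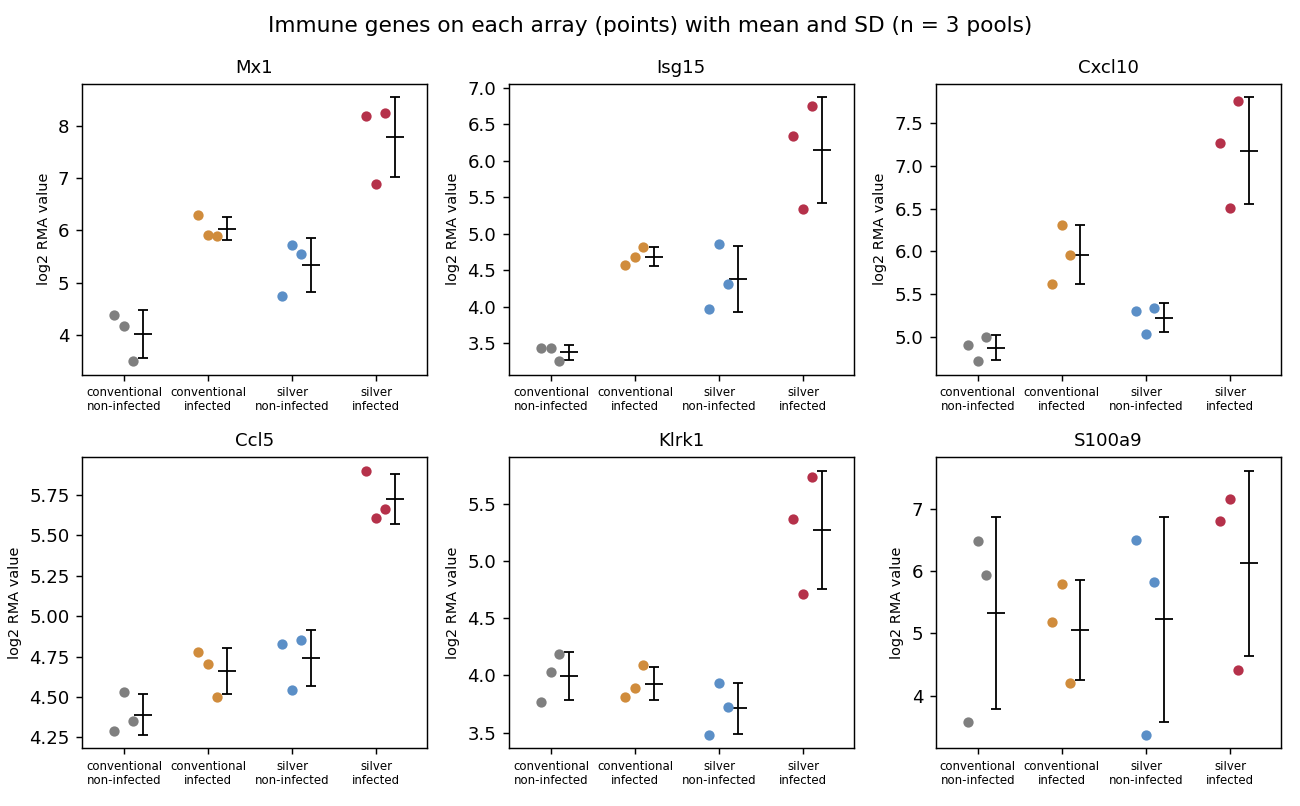
Each panel shows 1 immune gene, with the group on the horizontal axis and the log2 RMA value of each of 3 pools as points on the vertical axis, beside the mean and SD. Mx1 had means of 4.02 in the conventional non-infected, 5.34 in the silver non-infected, 6.03 in the conventional infected and 7.78 in the silver infected group. S100a9 ranged from 3.58 to 6.47 within the conventional non-infected pools alone.

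The interaction asks whether the silver difference depended on infection. With pools taken as independent it passed for Reg3g (3.21 ± 0.29 log2), Fabp6 (2.63 ± 0.33), Defa8 (2.51 ± 0.20), Reg3b (2.17 ± 0.24) and Defa9 (1.99 ± 0.24). These genes also passed in both comparisons of the infected silver group, which rest on the same infected silver arrays. Whether intestinal RNA in those pools raised them stays open, so a response to silver that depends on infection was not shown for them. Igfn1, named here outside the rule after its values were seen, had an interaction of 1.85 and was lower with silver in non-infected tissue (5.27 ± 0.11 SD, n = 3, against 6.84 ± 0.31 with the conventional mesh). Gabrr2 had an interaction of -1.66 ± 0.19, with group means of 4.09 in conventional non-infected and silver infected tissue and of 4.93 and 4.92 in conventional infected and silver non-infected tissue. These 7 genes were all that passed (limma, Benjamini-Hochberg adjusted p from 0.000379 for Defa8 to 0.00686 for Fabp6 among the 6 named by the rule). All 7 also passed with the consensus correlation. With array weights 14 passed. In limma 0 genes passed with the correlation of 0.667 (10 at an unadjusted p under 0.05, against 970 with independent pools).

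For 12 lists the silver difference depended on infection in camera with the preset correlation. It did so for 0 lists with an estimated one (3 at an unadjusted p under 0.05) or in fry. The largest medians, with camera adjusted p = 5.7e-08 and 2.88e-07, were those of inflammatory cytokines and chemokines, where all 23 members lay above 0 (0.79 log2, adjusted p = 0.433 with an estimated correlation), and of natural killer and cytotoxic cells (0.71, adjusted p = 0.268 with an estimated correlation). Members with the largest values were Il6 (2.90 ± 1.04), Cxcl6 (1.60 ± 1.33), Klrk1 (1.63 ± 0.32) and Nkg7, a granule protein of cytotoxic cells (1.31 ± 0.37), none past the limma threshold. The mean of the cytokine members, relative to all arrays, ranged from -0.75 to 0.94 within the conventional non-infected pools alone. Groups accounted for 16.2% of the variance of a score over 44 neutrophil and cytokine genes, against 27.3% expected with no effect and independent pools. Among interferon-stimulated genes (median 0.42, adjusted p = 0.433 with an estimated correlation) Cxcl11 and Ifit3 were both at 1.37. In the lists that fell, Scd (-2.16 ± 0.38) and Adipoq (-0.89 ± 0.44) led the adipocyte genes, and Eln (-0.60 ± 0.21) and Col14a1 (-0.46 ± 0.13) the collagen and matrix genes, again short of the threshold (adjusted p = 0.433 and 0.529 for the lists with an estimated correlation). The other called lists had medians of 0.49 for neutrophil, 0.46 for classically activated macrophage, 0.42 for macrophage, 0.34 for bacterial sensing, 0.30 for T cell, 0.26 for heat shock and unfolded protein and 0.19 for cell cycle genes. Each call was lost, with adjusted p = 0.529, 0.433, 0.433, 0.462, 0.268, 0.268 and 0.466 with an estimated correlation. With 1 array left out camera called the neutrophil and collagen lists in 6 of 12 fits and cell cycle genes in 8. It called the adipocyte, classically activated macrophage, bacterial sensing and T cell lists in 11. Without conventional non-infected replicate 1 the median was 1.34 for cytokines, 0.76 for classically activated macrophage and 0.32 for cell cycle genes. Without its replicate 2 it was 0.21 for neutrophil, 0.28 for macrophage, 0.24 for classically activated macrophage, 0.16 for bacterial sensing and 0.081 for cell cycle genes. Without silver non-infected replicate 1 it was 0.25 for interferon-stimulated and -0.019 for collagen genes, and without its replicate 2 it was 0.24 for neutrophil, 0.12 for cell cycle and -0.19 for collagen genes. Without conventional infected replicate 3 it was 0.29 for neutrophil and for classically activated macrophage genes. Without silver infected replicate 1 it was 0.44 for natural killer cells, and without replicate 2 it was 0.73 for interferon-stimulated and 0.31 for neutrophil genes. Without replicate 3 it was 0.19 for interferon-stimulated, 0.78 for neutrophil and -0.060 for collagen genes. In these lists, Lcn2 (2.34 ± 1.10), Csf3r (1.35 ± 0.74), Cd8a (1.42 ± 0.41), Chac1 (1.12 ± 0.28), Cd2 (1.00 ± 0.55), Clec4e (1.00 ± 0.74), Atf3 (0.85 ± 0.25), Tlr6 (0.80 ± 0.31), Vsig4 (0.75 ± 0.33), Aif1 (0.65 ± 0.35), Cdk1 (0.63 ± 0.28) and Rrm2 (0.43 ± 0.32) did not pass.

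**Figure D3:**
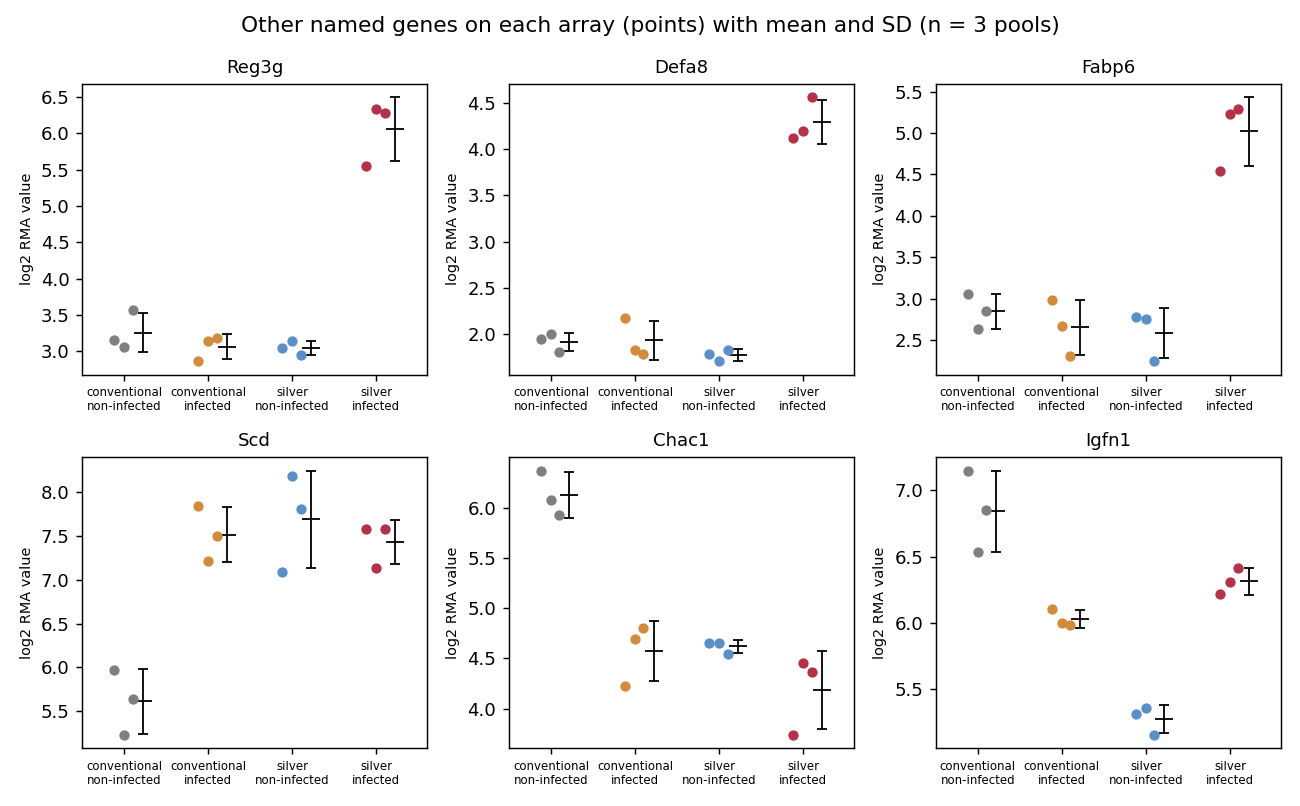
Each panel shows 1 gene, with the group on the horizontal axis and the log2 RMA value of each of 3 pools as points on the vertical axis, beside the mean and SD. Defa8 lay between 4.12 and 4.57 in the infected silver pools and between 1.70 and 2.18 in the other groups, while Chac1 lay between 5.93 and 6.37 in the conventional non-infected pools and between 3.74 and 4.80 in the others.

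Reference genes of acute bacterial inflammation differed little beside their spread. With the conventional mesh, infection changed S100a8 by -0.33 ± 0.72, S100a9 by -0.27 ± 0.94, the cytokine gene Il1b by -0.57 ± 0.92 and the bacterial lipoprotein receptor gene Tlr2 by -0.08 ± 0.32. With the silver mesh the changes were 0.84 ± 0.72, 0.89 ± 0.94, 0.62 ± 0.92 and 0.58 ± 0.32. Between infected meshes they were 0.80 ± 0.72, 1.06 ± 0.94, 0.62 ± 0.92 and 0.08 ± 0.32, and between non-infected meshes -0.37 ± 0.72, -0.10 ± 0.94, -0.57 ± 0.92 and -0.57 ± 0.32. Col1a1, Acta1 and Krt14, markers of collagen, muscle and epidermis, lay between -0.04 and 0.10 in those 4 comparisons. Adipoq, an adipocyte hormone, was at 1.18 ± 0.31 with silver in non-infected tissue (adjusted p = 0.272 with limma), at 0.25 ± 0.31 with infection of the conventional mesh, at -0.64 ± 0.31 with infection of the silver mesh and at 0.29 ± 0.31 between infected meshes. Mt2A was at -0.85 ± 0.47 and 0.62 ± 0.47 with infection of the conventional and the silver mesh and at 0.52 ± 0.47 between infected meshes. The interaction was 1.17 ± 1.02 for S100a8, 1.16 ± 1.32 for S100a9, 1.19 ± 1.30 for Il1b, 0.66 ± 0.45 for Tlr2, -0.04 ± 0.16 for Col1a1, 0.12 ± 0.16 for Acta1, 0.03 ± 0.32 for Krt14 and 1.46 ± 0.66 for Mt2A. None of these reference genes passed in any comparison (limma).

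Lists called by camera in no comparison had, with infection of the silver mesh, medians of 0.19 for matrix proteases and inhibitors, 0.19 for the myofibroblast and TGF-beta response, 0.18 for inhibitors of inflammation, 0.17 for metal response, -0.09 for oxidative stress, 0.01 for the alternatively activated macrophage, 0.10 for keratinocyte, -0.02 for skeletal muscle, -0.07 for mast cell, -0.24 for blood and -0.30 for Schwann cell genes. Their camera adjusted p lay between 0.0640 for the myofibroblast list and 0.689 for the alternatively activated macrophage and oxidative stress lists, with 0.0769 for metal response. The muscle regeneration list was not called here either (median 0.21, camera adjusted p = 0.0769), though its member Igfn1 rose (1.04 ± 0.14, limma adjusted p = 0.00985). In the other comparisons the smallest camera adjusted p of these 11 lists was 0.0619 for skeletal muscle with infection of the conventional mesh, 0.0596 for oxidative stress with silver in non-infected tissue and 0.0654 for the myofibroblast list between infected meshes. For the interaction it was 0.0710, for metal response (median 0.20) and Schwann cell genes (-0.24). Median, mean and test differed in sign only for lists that camera did not call in the comparison concerned. With infection of the conventional mesh these were the macrophage, classically and alternatively activated macrophage, bacterial sensing, T cell, adipocyte, keratinocyte and cell cycle lists. For silver without infection they were the foreign-body giant cell, T cell, matrix protease, keratinocyte and blood lists. Between infected meshes they were the alternatively activated macrophage, mast cell and skeletal muscle lists, and for the interaction the alternatively activated macrophage, protease and endothelial lists.

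The infection changes with the 2 meshes, which share no array, were weakly related across the 14557 genes (Pearson r = 0.191, Spearman rho = 0.152), as were the silver differences with and without infection (r = 0.134, rho = 0.138). Simulations with no effect, independent pools and genes drawn independently reached at most 0.0295 and 0.0276. Genes that move together would widen that range, so these maxima do not exclude chance. With 1 array left out r ranged from 0.0960 to 0.267 and from 0.0446 to 0.209. Spread between pools lowers such correlations, so low values do not show that the effects differ. Genes are not independent replicates, so no p-value is given. Tceal7 rose and Pfkfb3 fell with infection around both meshes, against 0.0181 and 0.000412 shared genes for independent calls. Both comparisons use the same variance estimate of a gene, so their calls are not independent even with no effect. The infection change with the conventional mesh and the silver difference without infection share their control arrays, and both had Scd higher and Chac1 lower. Their correlation was 0.588, against a mean of 0.500 in simulations with no effect, and their covariance 0.0316 against 0.0159. The 3 control arrays cannot be split with at least 2 on each side, so no split was made and part of the excess of 0.0157 may come from them.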

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

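The interaction test singled out 7 genes and 12 gene lists whose silver difference in infected tissue differed from that in non-infected tissue. Tests on intestinal genes were set before the values of the list tested were seen, but the reading that leaves a list median between the middle and the upper bound of random lists undecided was chosen after the result was seen. The rule set beforehand counted such a median against intestinal RNA and for induction, and that outcome was set aside.

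The genes were Reg3g (3.21 log2), Fabp6 (2.63), Defa8 (2.51), Reg3b (2.17), Defa9 (1.99), Igfn1 (1.85) and Gabrr2 (-1.66), all with a limma Benjamini-Hochberg adjusted p under 0.05. Of 100 splits of the arrays by mesh within each infection state, only the real one, 1 of 100, gave as many as 7 genes. The highest other gave 6. The labels imply that pools of a group share animals, which would by itself set the real split apart. These splits therefore cannot exclude chance for the count of genes.

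The lists that were higher had medians of 0.79 for inflammatory cytokines and chemokines, 0.71 for natural killer and cytotoxic cells, 0.49 for neutrophils, 0.46 for classically activated macrophages, 0.42 for macrophages, 0.42 for interferon-stimulated genes, 0.34 for bacterial sensing, 0.30 for T cells, 0.26 for heat shock and unfolded protein and 0.19 for the cell cycle. Adipocyte genes (-0.25) and fibrillar collagen and matrix (-0.12) were lower. For the count of 12 lists, 15 of 100 splits gave as many and the highest other gave 19, so chance cannot be excluded, and with an estimated correlation camera called 0 of them.

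In the comparisons of 3 arrays with 3 there are 10 splits, so the share cannot go below 0.1. For genes, the real count and the highest of the other splits were 8 and 0 for infection with the conventional mesh, 47 and 1 with the silver mesh, 3 and 0 for silver without infection and 24 and 0 between infected meshes, with 1 of 10 splits, the real one, as large in each. For lists they were 5 and 11 (6 of 10 splits as large), 14 and 16 (3 of 10), 5 and 18 (7 of 10) and 15 and 10 (1 of 10). Why a split of the non-infected arrays called 18 lists, several times the real count, was not tested. With an estimated correlation camera called 0 lists for the real groups of that comparison.

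The 10 intestinal genes seen were Defa6, Defa8, Defa9, Defa24, Reg3b, Reg3g, Reg4, Fabp6, Agr2 and Spink4. Each was higher in the 3 infected silver arrays than in the other 9, which held for 1.59% of all genes. Fabp6, Agr2, Reg4 and Spink4 are not defensins or Reg3 genes, but all 10 were picked for their values, so these were not used as a test.

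RNA of small intestine would raise other intestinal genes too, and the median of 32 others was 0.0811 log2, above 91.1% of 10000 random lists matched on level but below the upper bound set beforehand (0.11). Of the 32, 8 had an unadjusted p under 0.05, Itln1 passed (0.76, limma adjusted p = 0.0404) and Clca1 was at 1.35, while the enterocyte genes Fabp2 (0.03), Apoa4 (-0.07) and Vil1 (0.01) hardly differed. That bound was not taken to exclude intestinal RNA, since the genes called first were left out of the list. Most of the list also lies at low array values (infected silver means of 2.35 for Fabp2 and 2.16 for Apoa4). For the interaction the list median lay above 98.5% of random lists, the highest of the 5 comparisons. The interaction was not the comparison set beforehand and rests on the same infected silver arrays, so it adds no separate support. Intestine also holds lymphocytes and plasma cells, so the rises of Klrk1, Jchain and the T cell, natural killer and plasma cell lists in the same arrays were not separated from it. Over infected silver replicates 1, 2 and 3, Reg3g was at 5.55, 6.34 and 6.29 and Reg3b at 4.02, 3.67 and 3.66. Klrk1 was at 5.37, 4.71 and 5.74 and Jchain at 5.46, 5.67 and 5.50. With 3 pools, whether these genes move together was not tested. Intestinal RNA, which 1 animal present in all 3 pools could bring, and induction both stay open for the defensin and Reg3 genes. Induction of those genes alone would not cover Fabp6, Agr2, Reg4, Spink4 or Itln1.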

How the results depend on the processing

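The fits with pools correlated by the consensus and without intestinal genes were chosen after seeing the data. Genes called were 8 for infection with the conventional mesh (A), 47 for infection with the silver mesh (B), 3 for silver without infection (C), 24 for silver with infection (D) and 7 for the interaction (E). Quantile normalization again, median centring, the mean of a gene's clusters and a 1.5-fold minimum kept each of these counts within 1.5 times. So did the settings below for comparisons run with them and not named, but the fit of 2 groups has no E, and the fit without intestinal genes was run for B, D and E alone. Without the dimmest 30% of genes the counts were 18 in A and 13 in C, and the correlation of infection changes was 0.247. With all clusters they were 21 in B and 13 in D. A trended robust prior gave 57 in A, 111 in B and 14 in C. With only the 2 groups compared in the fit they were 19 in A, 11 in B and 8 in D. The replicate block gave 18 in B and 13 in D, but the replicate numbers do not pair the arrays: 3 of 18 same-number pairs correlated over 0.1 (mean -0.0261), and 2 of the 12 arrays correlated best with their own number. Array weights gave 23 in A, 267 in B, 17 in C and 14 in E. Pools correlated by 0.667 gave 0 in all 5, since each SE rises 2.65 times, and the consensus correlation gave 3 in A, 15 in B, 1 in C and 9 in D. Without intestinal genes, which removes called genes and raises the adjusted p of the others with their log2 changes as before, the counts were 22 in B, 1 in D and 2 in E. Lists called (5, 14, 5, 15 and 12 in A to E) were 0, 2, 0, 0 and 0 in camera with an estimated correlation and 0, 5, 0, 6 and 0 in fry. With pools correlated by 0.667, fry called 0 in all 5 (0 at an unadjusted p under 0.05), with smallest adjusted p of 0.965, 0.738, 0.957, 0.957 and 0.930. For the other shifts the cause was not tested. Signal over background was not used here, so low values cannot be called absent.

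With each array left out in turn, genes called ranged from 1 to 20 in A, 12 to 62 in B, 1 to 6 in C, 8 to 39 in D and 7 to 12 in E. Counts in A were 19 and 5 without conventional non-infected replicates 1 and 3, 15 and 20 without silver non-infected 1 and 2, and 1, 2 and 4 without conventional infected 1, 2 and 3. In B they were 24 without conventional non-infected 3, 31 and 13 without silver non-infected 2 and 3, 31 and 21 without conventional infected 2 and 3, and 12 without silver infected 1 or 3. In C they were 1 without replicate 3 of any group, 5 without conventional infected 1 or 2, and 6 without silver non-infected 2. In D they were 10 without conventional non-infected 3, 15, 15 and 12 without silver non-infected 1, 2 and 3, 15, 10 and 8 without conventional infected 1, 2 and 3, and 9, 39 and 13 without silver infected 1, 2 and 3. In E the count was 12 without conventional non-infected 1. Lists called ranged from 3 to 9 in A, 5 to 11 in C and 7 to 16 in E, with 9 in A and 11 in C without conventional non-infected 1, 3 in A and 8 in C without its replicate 3, and 7 in E without its replicate 2. The correlation of infection changes ranged from 0.0960 without conventional non-infected 1 to 0.267 without its replicate 2, with 0.142 without silver non-infected 2 and 0.148 without conventional infected 2. That of silver differences ranged from 0.0446 without silver non-infected 1 to 0.209 without its replicate 2, with 0.0577 without conventional non-infected 1.

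Of 53 calls of named genes, 23 held in every fit without an array of the groups compared: Pfkfb3 in A, Defa8, Defa9, Reg3b, Reg3g, Reg4, Fabp6 and Cxcl11 in B, Igfn1 in C, the same 6 intestinal genes with Agr2 and Ccl5 in D, and all 6 named by the rule in E. Of 51 list calls, 31 held in every fit without an array. The adjusted p of the other 20 is that of camera in the fits that lost them, with arrays named by mesh, infection and replicate number. In A, giant cell genes were lost without conventional non-infected 3 (0.0528) and conventional infected 2 (0.0929) and 3 (0.0585), and muscle regeneration without conventional non-infected 2 (0.121) and 3 (0.0528) and conventional infected 3 (0.0598). In B, neutrophil, adipocyte and oxidative phosphorylation genes were lost without silver non-infected 2 (0.682, 0.106 and 0.645), and the neutrophil and oxidative lists also without silver infected 1 (0.122 and 0.212) and 2 (0.251 and 0.0854). In C, cytokines were lost without conventional non-infected 2 (0.502) and silver non-infected 2 (0.358), adipocyte genes without silver non-infected 2 (0.355) and collagen without silver non-infected 1 (0.0642). In D, MHC class II (0.0542) and wound growth factors (0.0980) were lost without conventional infected 1. Neutrophil (0.236), vascular (0.0543) and cell cycle genes (0.0599) were lost without conventional infected 3. Neutrophil (0.0817) and vascular genes (0.0693) were lost without silver infected 1, and neutrophil (0.243), wound growth factors (0.0653), vascular (0.295) and cell cycle genes (0.243) without silver infected 2. In E, without conventional non-infected 2, neutrophil (0.231), classically activated macrophage (0.0556), bacterial sensing (0.143), T cell (0.0564) and cell cycle genes (0.228) were lost. Neutrophil genes in E were also lost without conventional non-infected 3 (0.0913), silver non-infected 2 (0.372), conventional infected 3 (0.161) and silver infected 1 (0.0849) and 2 (0.169). Collagen was lost without conventional non-infected 1 (0.0936) and 3 (0.0577), silver non-infected 1 (0.322), conventional infected 2 (0.0516) and 3 (0.0695) and silver infected 3 (0.173). Adipocyte genes were lost without silver non-infected 2 (0.0586), and cell cycle genes without silver non-infected 2 (0.133), conventional infected 3 (0.0616) and silver infected 2 (0.149). Values that changed sign belonged to reference genes that never passed. In A, S100a8 ranged from -0.75 to 0.22, S100a9 from -1.14 to 0.30, Il1b from -1.69 to 0.18, Tlr2 from -0.49 to 0.21, Acta1 from -0.10 to 0.079 and Krt14 from -0.10 to 0.24. In B, S100a9 ranged from -0.034 to 1.75, Il1b from -0.17 to 1.20, Col1a1 from -0.024 to 0.14 and Krt14 from -0.065 to 0.32. In C, S100a8 ranged from -0.84 to 0.32, S100a9 from -0.97 to 0.83, Il1b from -1.69 to 0.22, Col1a1 from -0.0026 to 0.16, Acta1 from -0.063 to 0.028 and Krt14 from -0.16 to 0.076. In D, Tlr2 ranged from -0.0054 to 0.16, Acta1 from -0.012 to 0.17 and Krt14 from -0.20 to 0.24. In E, Col1a1 ranged from -0.11 to 0.055 and Krt14 from -0.17 to 0.27, and Col1a1 was at 0.035 with quantile normalization again.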

Other observations

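Tests of the differences between pools and of the shared control arrays were chosen after the results were seen, and the genes of the next paragraph are named outside the rule, after their values were seen.

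Further genes passed with infection around the silver mesh. Interferon-induced genes were Ifi44 (1.09 log2), Gbp6 (1.09), Ifi47 (0.97), Rtp4 (0.81), Adar, an RNA-editing deaminase (0.65), Epsti1 (0.62) and Slfn9 (0.61). Immune genes were Tnfrsf14, a receptor of lymphocytes (1.40), Fcrl2 (1.14), Rac2, a GTPase of blood cells (1.06), Lgals3bp (0.99) and RT1-T24-3 (0.89). Others were Csrp3 (0.86), Ankrd2 (0.70), Igfn1 (1.04), Rras2 (0.69), Tecrl (1.15), Ppp1r14c (0.75), Aldh1a1, which makes retinoic acid (1.15), coagulation factor F10 (1.14) and Hamp, the iron-regulating hormone hepcidin (0.72). Each had a limma Benjamini-Hochberg adjusted p under 0.05. Between infected meshes Slfn1 (1.38) and Serpina3n (0.63) passed as well.

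Isg15 and Cxcl10, like Mx1, had their lowest mean in conventional non-infected tissue, followed by silver non-infected, conventional infected and silver infected tissue. Isg15 had means of 3.37 ± 0.11 (SD, n = 3) in conventional non-infected, 4.38 ± 0.45 in silver non-infected, 4.69 ± 0.13 in conventional infected and 6.15 ± 0.72 in silver infected tissue, and Cxcl10 had 4.88 ± 0.15, 5.23 ± 0.17, 5.96 ± 0.34 and 7.17 ± 0.62. Gbp1, Ifit3, Cxcl11 and Irf7 had other orders of the first 3 groups, with the silver infected mean highest. The order itself was not tested.

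Inflammatory genes differed between pools of a group. A score over 44 neutrophil and cytokine genes ranged over 0.66 to 1.47 log2 units within a group, and the group means lay within 0.48 of each other. Groups accounted for 16.2% of the variance of this score, against 27.3% expected with no effect and independent pools. Animals shared between pools of a group would raise the expected share. Infection and mesh are the same for all pools of a group, so neither was tested as a source of the differences within a group. In 65 of 74 cases of a gene and group with a range of at least 1 log2 unit, 87.8%, the odd pool was the low one, against 48.6% for all other genes. This is consistent with 1 animal of each group with high inflammatory transcripts that is shared by 2 of its 3 pools, as a hypothesis, and since these genes move together the cases amount to little more than the 4 groups.

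Scd was lower and Chac1 higher in the conventional non-infected arrays than in the conventional infected and the silver non-infected ones. Changes against these arrays ran together across genes, with a covariance of 0.0316, above the highest of 100 simulations with independent pools (0.0170), and above that value raised for the consensus pool correlation (0.0216). These simulations drew each gene independently, while genes that move together across pools would widen the spread of the covariance. They therefore cannot exclude independent pools, or pools correlated by that consensus, as its source. A correlation of 0.667 in every gene would allow more (0.119), but simulations with it gave 43.3% of genes an unadjusted p under 0.05 for infection of the conventional mesh, against 9.07% here. A correlation of 0.247 between the control pools would give the covariance seen. What the animals of a group share is confounded with the group, so the shared control arrays cannot be told apart from a response common to infection and silver.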
